A study of Mus musculus with 14 samples.

How the data were processed

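The series holds 14 samples. Bulk RNA-seq of mouse bone marrow-derived macrophages compares 4 libraries with siSpp1 against 4 with vehicle, and single-nucleus RNA-seq of left atria compares anti-Trem2-siSpp1 with vehicle in 6 samples, of which 4 were used and the other 2 were not analysed here. Groups and replicate numbers were taken from the sample labels.

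For the macrophages the deposited values are CPM in 1 table for all 8 libraries. Per the submitters' processing notes, the reads were quantified with Salmon 1.10.0 against GRCm39 and handled with edgeR 4.6.3, and per the labels the table is TMM-normalised CPM with offsets. The libraries were stranded poly(A) libraries. Whole reads could not be recovered from these values: 40.4% to 48.8% of the low values per library were whole multiples of the smallest step at a tolerance of 0.02. The planned count test on recovered reads was therefore not run, and the depth of these libraries is unknown. Of 35667 gene identifiers, 35104 were matched to a symbol by identifier, 69 by another table and 494 had none. Only GRCm38 annotation (GENCODE M21) was used here, so no coordinates are given for the bulk data, and it served only for the GC content and 3' untranslated regions of genes.

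For the nuclei the deposited values are counts of UMIs for every barcode, unfiltered, from 10x Genomics 3' v3.1 libraries; per the submitters' processing notes they were made with Cell Ranger 7.1.0 against mm10. Cell classes were rebuilt from these counts and can differ from the submitters' own. Identifiers that share a symbol were represented by the most abundant one.

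The macrophage libraries were compared with limma 3.58.1 (R 4.3.3) on log2(CPM + 1) with a mean-variance trend, for the 11063 genes with at least 1 CPM in at least 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05; all tests are two-sided. A fold change on this scale understates the change of genes near or below the pseudocount of 1. Gene lists, 29 for the macrophages and 27 for the nuclei, were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, then with an estimated correlation, and in the bulk data with fry; members past the threshold were counted over all genes and adjusted over the list alone. The designs, lists, markers, the rule for the genes named in the text and most alternatives were fixed before the data were examined; the scoring that names clusters was not (below). The rule for genes named Spp1 and Trem2; in the bulk data the 10 largest increases and 10 largest decreases among called genes of at least 5 CPM whose groups did not overlap; in each nuclear class up to 6 genes per direction past the threshold, or the 3 with the smallest p where fewer passed; and up to 3 members with the smallest p from each bulk list and from each nuclear list past the threshold. Genes with provisional names, mitochondrial and ribosomal protein genes, pseudogenes and X-inactivation or Y-linked genes were left out of it, and 2 results on single genes are not reported here.

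Barcodes were kept with at least 500 UMIs, at least 300 genes and at most 5% mitochondrial UMIs, which left 997 (anti-Trem2-siSpp1 replicate 1), 2911 (anti-Trem2-siSpp1 replicate 3), 10443 (vehicle replicate 4) and 8532 (vehicle replicate 7). Scrublet, run in scanpy 1.11.5, called 3, 2, 0 and 1 doublets in these libraries, too few to count as having worked, so doublets remain; an alternative removed the highest 5% of scores per library. Counts were scaled to 10000 per nucleus and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method of igraph 0.11.9 at a resolution of 1. Without integration it gave 20 clusters. A marker counted as raised in a cluster at a level of at least 0.3 per 10000 and a log2 fold above 1 over the median of the other clusters, computed within each library with at least 10 nuclei and taken as the median over libraries. A cluster took the class with the largest share of raised markers, given at least 3. Endothelial clusters with at least 3 raised endocardial or lymphatic markers took those names. This scoring rule is the third of 3 versions, kept after the results of the first 2 had been seen. Clusters with a median mitochondrial share above 3% were set aside, a rule set after the clusters were seen; it removed 238, 2513, 428 and 77 barcodes in the order above and is what left too few cardiomyocyte-like nuclei for the planned test. No other version of the naming rule and no version without the set-aside rule gave a called gene in edgeR's test.

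UMI counts were summed per library and class, for classes with at least 20 nuclei in each library, and tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test) with Benjamini-Hochberg adjustment within the class; DESeq2 1.42.0 was the other tool. The 7 classes tested were endocardial-, endothelial-, fibroblast-, macrophage-, mesothelial-, B- and T or NK-like nuclei, with 0 genes past edgeR's threshold in each. Endocardial-, mesothelial-, B- and T or NK-like nuclei had 590, 545, 48 and 183 genes at an unadjusted p under 0.05 by edgeR and were not run with DESeq2. Spp1 did not pass filterByExpr in macrophage-like nuclei and is given as summed counts with exact Poisson intervals. Shares of nuclei have exact binomial 95% intervals and an exact permutation test, whose smallest p with 2 against 2 libraries is 0.333. The spread against which alternatives for the shares were judged, and the pooled form of the Spp1 ratio, were set after the values were seen.

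The bulk and nuclear tests were run first on simulated data with 200 changed genes. In the nuclear simulation all genes of a class had a common dispersion, the spread beyond counting. All libraries shared the same mean profile, so differences in quality or free RNA between them were absent and recovery can be overstated. For the bulk comparison 90% of genes changed by -0.5 on the log2 scale, 56% at -0.2, 38% at 0.2 and 88% at 0.5 were recovered, with 5 false among 141 calls. The alternatives covered the pseudocount, filters, scaling, the limma settings, a replicate block, the camera variants, thresholds for nuclei, clustering resolution, ComBat by library, subtraction of free RNA from nearly empty droplets, thinning to equal depth, and each library left out in turn. Where 1 library remains in a group, it is assumed to vary like the other group's libraries. Alternatives added after seeing the data were the removal of a GC content trend, free RNA estimated from barcodes with 100 to 500 UMIs, removal of high doublet scores, other versions of the naming and set-aside rules, a mitochondrial limit of 10% and ComBat for the tests of genes, the larger macrophage-like cluster alone, and the shares with each library left out. In comparing settings, a sign change of a list or gene past the threshold in neither setting was not counted as a change.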

Results

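The series asks what happens when Spp1, the gene for the secreted matrix protein osteopontin, is silenced in macrophages, in the setting of atrial fibrillation. It holds 14 samples from 2 experiments. In the first, bone marrow-derived macrophages of C57BL/6 mice were grown for 5 days in 30 ng/mL M-CSF and polarised for 24 hours with IL-4 and IL-13 at 10 ng/mL. They then received either an siRNA against Spp1 (siSpp1) in lipofectamine or lipofectamine alone (vehicle) for 24 hours, with 4 libraries of poly(A) RNA per group. In the second, single-nucleus RNA-seq was made from left atria of HOMER mice, a model of hypertension, obesity and mitral valve regurgitation. These mice received vehicle or anti-Trem2-siSpp1, named for an antibody against the macrophage receptor Trem2 and an siRNA against Spp1, with 3 mice per group. Of these 6 samples 4 were analysed, anti-Trem2-siSpp1 replicates 1 and 3 and vehicle replicates 4 and 7, and the other 2 were not analysed here. The macrophage table listed 35667 genes in CPM, normalised counts scaled to a common library size, with sums of 990021 to 1015810 per library. Between 16390 and 16720 genes lay above 0, and the number of reads behind each library is not known. The nuclei libraries held 10116685 (anti-Trem2-siSpp1 replicate 1), 30534044 (replicate 3), 33583550 (vehicle replicate 4) and 16952322 (vehicle replicate 7) UMIs over all barcodes.

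The first comparison asks which genes respond to siSpp1 in cultured macrophages. Spp1 itself fell by 2.03 on the log2 scale (SE 0.0285), from 6135 ± 185 CPM (SD, n = 4) in vehicle to 1500 ± 44.2 CPM (SD, n = 4) in siSpp1 cultures. Against that change, the rest of the transcriptome moved little. Of 11063 genes tested, 65 rose and 38 fell, by a median of 0.19 in absolute log2 change, and no increase exceeded 0.34. The second largest decrease among genes of at least 5 CPM was in Tm4sf19, which encodes a tetraspan membrane protein and fell by 1.03 (SE 0.0571; 14.8 ± 1.22 to 6.75 ± 0.225 CPM). Trem2, the lipid-sensing receptor used for targeting in the atrial experiment, had a log2 change of -0.03 (SE 0.0267), with 830 ± 27.4 CPM in vehicle and 815 ± 18.1 CPM in siSpp1 cultures.

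**Figure D1:**
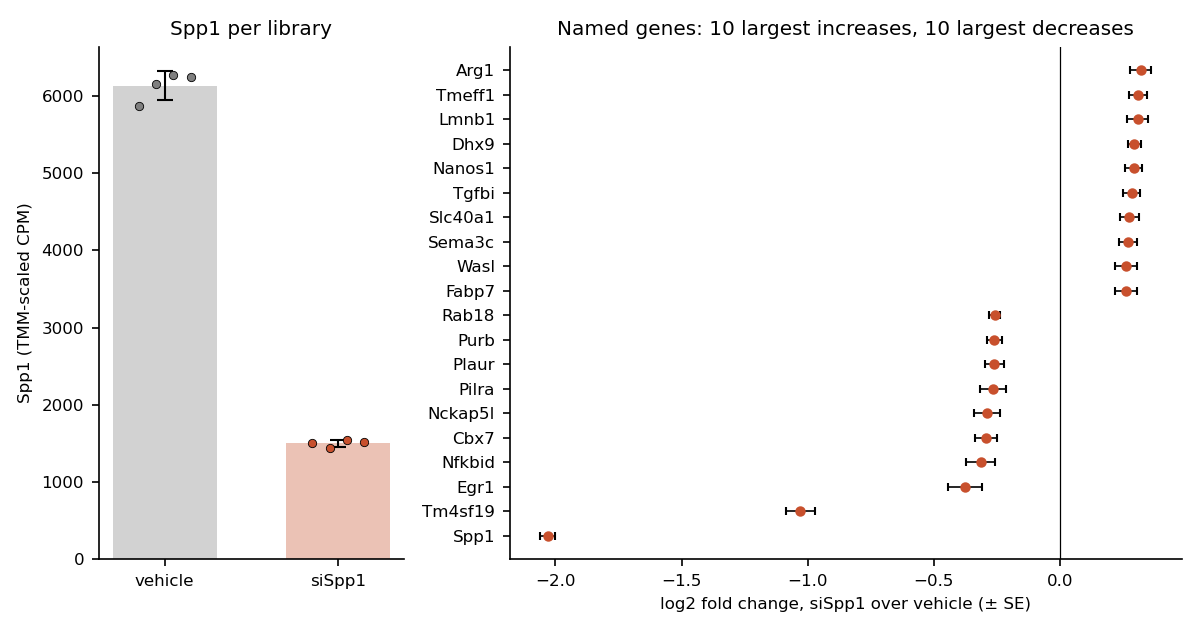
Left, Spp1 in CPM in each of the 8 macrophage libraries (points) with the group mean (bars) and SD; the siSpp1 libraries average 1500 CPM against 6135 CPM in vehicle. Right, log2 fold change (siSpp1 against vehicle) with its SE for the 10 named genes with the largest increases and the 10 with the largest decreases, which run from 0.32 for Arg1 to -2.03 for Spp1.

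Among the genes that rose was Arg1, the arginase of alternatively activated macrophages (log2 change 0.32, SE 0.0429, 128 ± 8.94 to 160 ± 2.88 CPM). So did Tgfbi, a TGF-beta-induced matrix protein (0.29, SE 0.034, 140 ± 6.39 to 171 ± 4.86 CPM), and Slc40a1, the iron exporter ferroportin (0.28, SE 0.0378, 110 ± 6.63 to 133 ± 2.09 CPM). Dhx9, an RNA helicase, rose by 0.30 from 152 to 187 CPM. The other named increases were in Tmeff1 (0.31), the nuclear lamin gene Lmnb1 (0.31) and the RNA-binding regulator Nanos1 (0.29), followed by the secreted semaphorin Sema3c (0.27), the actin nucleation factor Wasl (0.26) and the fatty acid-binding protein gene Fabp7 (0.26). Besides Spp1 and Tm4sf19, the named decreases were in the immediate early transcription factor Egr1 (-0.38, SE 0.0691, 17.7 ± 1.95 to 13.4 ± 0.553 CPM), the NF-kB regulator Nfkbid (-0.31), the polycomb protein gene Cbx7 (-0.29) and Nckap5l (-0.29). The others were the inhibitory receptor Pilra (-0.26), the urokinase receptor Plaur (-0.26, 152 to 127 CPM), the nucleic acid-binding protein gene Purb (-0.26) and the small GTPase gene Rab18 (-0.26). On the scale of log2(CPM + 1), no gene rose and 5 genes fell by more than 1.5-fold. Apart from Spp1 and Tm4sf19 these were Pagr1a (-1.52, from 3.75 to 0.581 CPM), Gm20056 (-0.95, from 3.94 to 1.56 CPM) and Gm10925 (-0.59), which lie outside the naming rule and were singled out after their values were seen. Spp1, Pagr1a and Tm4sf19 fell by more than 2-fold on this scale, which understates the fold of genes with few CPM, and Gm20056 did so in CPM.

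Of the 14 members of the list for the NRF2 response to oxidative stress, 3 rose over all genes tested and 5 when adjusted over the list alone, with a list median of 0.07 (limma camera, adjusted p = 2.6e-06; p = 0.0026 and adjusted p = 0.0628 with an estimated correlation). The 3 were Srxn1, a sulfiredoxin (log2 change 0.17, 310 to 348 CPM), Gclm, a subunit of the enzyme that limits glutathione synthesis (0.19, 304 to 347 CPM), and the cystine transporter Slc7a11 (0.26, 42.4 to 51.0 CPM). Cell cycle genes had a median of 0.10 over 28 members (camera adjusted p = 2.6e-06; adjusted p = 0.562 with an estimated correlation), with 0 called over all genes by limma and 5 higher adjusted over the list alone. These included the DNA replication licensing genes Mcm5 (0.12) and Mcm7 (0.13) and the cyclin gene Ccne2 (0.27). Cholesterol synthesis genes had a median of 0.04 over 24 members (camera adjusted p = 0.0365; adjusted p = 0.562 with an estimated correlation), with 0 called over all genes and 2 higher adjusted over the list alone, the sterol transporter Stard4 (0.17) and the synthase Hmgcs1 (0.11). Antigen presentation class II genes had a median of -0.11 over 7 tested members (camera adjusted p = 0.0365; adjusted p = 0.562 with an estimated correlation). None of these was called by limma over all genes or over the list alone, with -0.16 for the invariant chain Cd74 and -0.11 for the peptide-loading gene H2-DMa. The osteoclast list, genes of the bone-resorbing relatives of macrophages, had a median of -0.06 over 10 tested members (camera adjusted p = 0.0365; adjusted p = 0.562 with an estimated correlation). None of its members was called by limma over all genes, and 1 was higher and 3 lower adjusted over the list alone, with -0.39 for the gelatinase Mmp9 (32.8 to 24.7 CPM), -0.21 for the fusion protein gene Dcstamp and -0.33 for Ocstamp.

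The lists for osteopontin-associated macrophages, alternative activation, growth factors and osteopontin receptors did not pass camera, and the last of them passed fry. The osteopontin-associated macrophage list, with 20 tested members, had 0 genes called over all genes by limma (list median -0.02, camera adjusted p = 0.903). Adjusted over the list alone 1 was higher and 1 lower, with 0.09 for the elastase Mmp12 and -0.16 for the fatty acid-binding protein gene Fabp5. Of 17 tested genes of alternative activation by IL-4 and IL-13, Arg1 rose and 16 did not pass the test (median -0.02, camera adjusted p = 0.607). Adjusted over the list alone, 2 were higher and 3 lower, with -0.40 for the growth factor gene Hbegf and -0.13 for the receptor gene Il4ra. Among 26 growth factors and matrix regulators, Tgfbi and the growth factor gene Igf1 (0.14, 1436 to 1577 CPM) rose and Plaur fell, with 5 higher and 4 lower adjusted over the list alone (median 0.02, camera adjusted p = 0.263). Of 9 osteopontin receptor genes, the integrin subunit gene Itga5 rose (0.18, 345 to 391 CPM), and 4 were higher and 1 lower adjusted over the list alone (median 0.05, camera adjusted p = 0.0568; fry adjusted p = 0.0323).

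The inflammatory and interferon lists did not pass camera. The type I interferon list had a median of 0.14 over 28 tested members (camera adjusted p = 0.0568; adjusted p = 0.689 with an estimated correlation). Its members included the chemokine gene Cxcl10 at 0.33 and Oas2 at 0.16, and limma called 0 over all genes or over the list alone. The NF-kB list had a median of -0.06 over 19 (camera adjusted p = 0.0682), and the list of RNA interference and double-stranded RNA sensing had -0.04 over 16, with 1 higher adjusted over the list alone, Cgas at 0.20 (camera adjusted p = 0.345). Single members rose or fell in lists that did not pass. Srebf1, a regulator of lipid synthesis, fell in the LXR and lipid efflux list (-0.24, 56.3 to 47.4 CPM), whose median was -0.11 with 1 higher and 3 lower adjusted over the list alone. With the same adjustment given for each list, Ccng1 rose in the p53 list (0.11, median 0.02, 1 higher and 1 lower), Pdia6, a protein disulfide isomerase, rose in the unfolded protein and integrated stress response list (0.16, median 0.01, 2 higher), and Egr1 fell in the immediate early list (median -0.02, 2 lower). In the lists for lysosome (median -0.02), class I antigen presentation (-0.04), glycolysis and hypoxia (-0.02) and oxidative phosphorylation (-0.01), 0 genes were called over all genes or over the list alone. Efferocytosis and phagocytosis (-0.02) had 1 gene higher over the list alone, and heat shock (-0.02) had 3 lower, among them Hspa1b at -0.33. Among markers of other cells, the list medians were -0.01 for monocyte and 0.13 for fibroblast or stroma, and, with fewer than 5 tested members, neutrophil -0.10, dendritic -0.07, mast or basophil 0.08, lymphoid -0.01 and erythroid or megakaryocyte -0.01.

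Calls came from limma on log2(CPM + 1) with Benjamini-Hochberg adjustment (adjusted p = 6.5e-11 for Spp1, 2.9e-05 for Tm4sf19 and 0.725 for Trem2), and 1567 genes had an unadjusted p under 0.05. In each of the 103 called genes the 4 vehicle and 4 siSpp1 values did not overlap; 9.23% of all tested genes were apart in this way, where chance gives 2.86%. Of the 24 lists with at least 5 tested members, 5 passed camera with the preset correlation, 0 did with an estimated one, and 2 passed fry. The control received the transfection reagent without an siRNA, so the values hold the effect of carrying any siRNA together with that of losing Spp1. The counts of 65 and 38 became 21 and 10 without siSpp1 replicate 3, 23 and 12 without siSpp1 replicate 2, and 29 and 14 without siSpp1 replicate 1. They were 35 and 15 without vehicle replicate 4, 38 and 22 without vehicle replicate 3, and 39 and 24 without vehicle replicate 2, and with all 8 libraries 37 and 18 without limma's trend, 45 and 15 without the filter on low values, and 2 and 5 with replicate number as a block.

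The second experiment asks what anti-Trem2-siSpp1 changes in the left atrium. The libraries differed in quality before any comparison of cell types. Of the barcodes with at least 500 UMIs, the median mitochondrial share was 7.40% and 8.43% in anti-Trem2-siSpp1 replicates 1 and 3, against 2.45% and 2.55% in vehicle replicates 4 and 7. In the same order, 73.3%, 86.9%, 13.2% and 10.0% of them lay over the limit of 5%. After filtering, 997, 2911, 10443 and 8532 barcodes remained, with median UMIs of 3966, 1683, 1567 and 808. A further 23.9%, 86.4%, 4.10% and 0.903% of these sat in 2 clusters with a median mitochondrial share above 3% and were set aside. The first had cardiomyocyte markers (2513 barcodes in anti-Trem2-siSpp1 replicate 3), and the other was led by haemoglobin, albumin and immunoglobulin genes (225 barcodes in anti-Trem2-siSpp1 replicate 1). Cell classes were named for 756, 396, 10015 and 8454 nuclei.

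Under the naming and set-aside rules used, endocardial-like nuclei were the most frequent class in each library. They made up 30.4 ± 0.451% of named nuclei in the treated libraries and 48.8 ± 9.89% in vehicle (mean ± SD, n = 2 each). They did not come from the same cluster: 208 of the 232 in anti-Trem2-siSpp1 replicate 1 formed a cluster that held 1, 8 and 1 nuclei of the other 3 libraries. Under the second version of the naming rule that cluster was endothelial-like. With clusters kept in the class of their markers, 2513 cardiomyocyte-marker barcodes outnumbered the 119 endocardial-like nuclei of anti-Trem2-siSpp1 replicate 3. Macrophage-like nuclei made up 18.3% (exact binomial 95% interval 15.6 to 21.2) and 5.05% (3.11 to 7.69) of the named nuclei in anti-Trem2-siSpp1 replicates 1 and 3, and 4.34% (3.95 to 4.76) and 13.2% (12.5 to 13.9) in vehicle replicates 4 and 7. The means of 11.7 ± 9.34% and 8.75 ± 6.24% thus differed by less than the spread within either group (exact permutation test, two-sided, p = 0.667). The difference of 2.90 points turned to -3.70 without anti-Trem2-siSpp1 replicate 1 and to -1.51 without vehicle replicate 4. It grew without anti-Trem2-siSpp1 replicate 3, without vehicle replicate 7 and with ComBat by library. A smaller cluster with 5 of 14 macrophage markers raised gave 69 of the 138 macrophage-like nuclei of anti-Trem2-siSpp1 replicate 1. It gave 4 of 20 in replicate 3, and 100 of 435 and 130 of 1113 in vehicle replicates 4 and 7. Fibroblast-like nuclei were at 12.1 ± 1.04% in treated and 17.7 ± 3.69% in vehicle libraries, endothelial-like at 6.22 ± 0.935% and 6.52 ± 0.787%, and cardiomyocyte-like at 6.40 ± 7.74% and 1.79 ± 0.697%. B-like nuclei were at 6.69 ± 1.96% against 0.490 ± 0.143%, and T or NK-like nuclei at 12.8 ± 8.26% against 1.70 ± 0.739%. The exact permutation test of 2 against 2 libraries cannot give a p below 0.333, which was the value for fibroblast-like, endocardial-like, B-like and T or NK-like nuclei. The clusters set aside and the gap in mitochondrial share can set these shares, and the intervals cover counting error only.

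**Figure D2:**
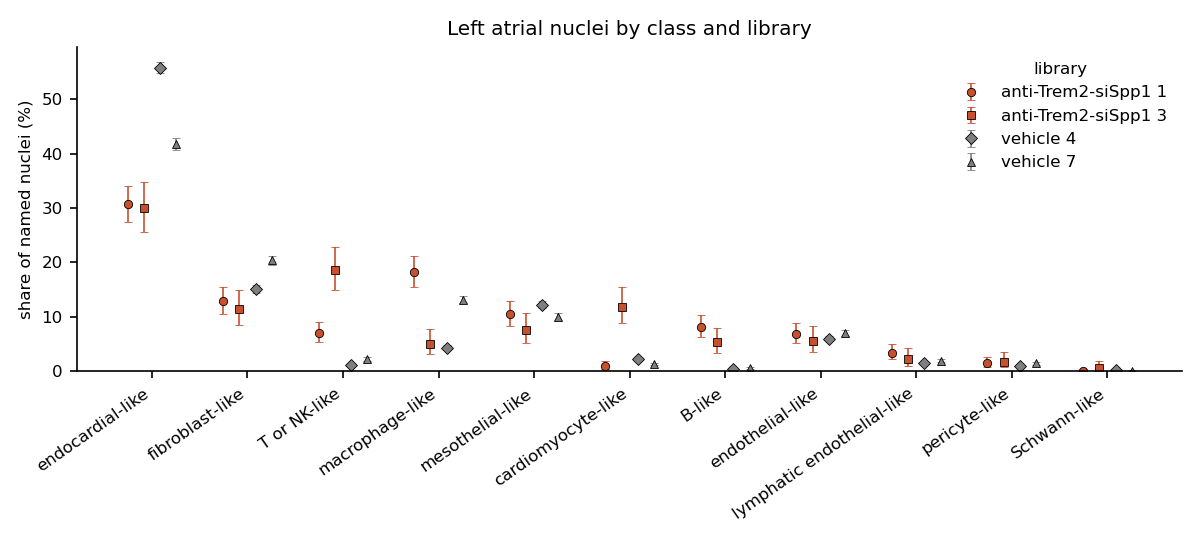
Share of named nuclei (percent) in each class for the 4 left atrial libraries, with exact binomial 95% intervals that cover counting error only. Macrophage-like nuclei run from 4.34% in vehicle replicate 4 to 18.3% in anti-Trem2-siSpp1 replicate 1, and the vehicle replicates differ from each other as well.

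Spp1 (chromosome 5, 104435118 to 104441050, plus strand, GRCm38) was rare in macrophage-like nuclei of all 4 libraries. Anti-Trem2-siSpp1 replicate 1 held 5 Spp1 UMIs among 138 macrophage-like nuclei, or 5.76 CPM of the summed UMIs (exact Poisson 95% interval 1.87 to 13.4). Replicate 3 held 0 among 20 nuclei (exact interval 0 to 40.8 CPM). Vehicle replicate 4 held 10 among 435 nuclei (9.73 CPM, 4.67 to 17.9) and vehicle replicate 7 held 31 among 1113 nuclei (23.003 CPM, 15.6 to 32.7). Pooled by group this is 5.22 against 17.3 CPM, a log2 ratio of -1.73 (exact counting interval -3.42 to -0.39). The interval is for counting error only, and the ratio was -0.90 (-2.80 to 0.78) without vehicle replicate 7 and -1.58 without anti-Trem2-siSpp1 replicate 3. With the libraries as replicates, edgeR without the filter on low counts gave a log2 change of -1.71 (unadjusted p = 0.0469). It did not pass when adjusted over all genes (edgeR adjusted p = 0.64). For this preset gene the plan was the unadjusted p, but no test where the filter removed it, as here. Without anti-Trem2-siSpp1 replicate 1 no treated UMI is left. Nearly empty barcodes of 10 to 100 UMIs also held Spp1, at 9.33 and 17.95 CPM in vehicle replicates 4 and 7 (8 and 78 UMIs). Both values lie within the intervals of macrophage-like nuclei of the same libraries. The much smaller treated profiles of 33377 and 24868 UMIs held 0 Spp1 UMIs. Trem2 was at 9.33 and 34.98 CPM in the same vehicle profiles (8 and 152 UMIs), with 0 UMIs in the treated ones. Trem2, the antibody's target, stood at 46.1 and 11.1 CPM (40 and 1 UMIs) in the treated and 48.7 and 59.4 (50 and 80 UMIs) in the vehicle libraries, with a log2 change of -0.45 (edgeR adjusted p = 0.923).

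**Figure D3:**
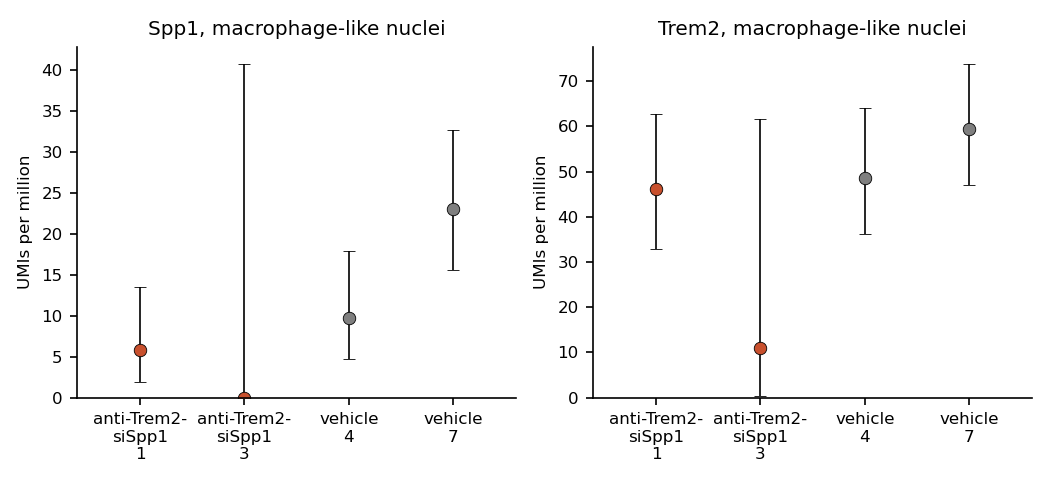
Spp1 and Trem2 in CPM of the summed UMIs in macrophage-like nuclei of each left atrial library, with exact Poisson 95% intervals that cover counting error only. Spp1 lies at 5.76 and 0 in the treated and 9.73 and 23.003 in the vehicle libraries, and the interval of anti-Trem2-siSpp1 replicate 3, with 20 nuclei, reaches 40.8.

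In macrophage-like nuclei the treated libraries had lower values for the resident macrophage list and higher values for class II antigen presentation. Of 19 tested resident macrophage genes, the mannose receptor gene Mrc1 was at 631 and 681 CPM in treated and 1355 and 1324 CPM in vehicle nuclei (log2 change -1.04, SE 0.308). Timd4, a receptor for dying cells, went the other way at 1.33 (SE 0.328). The list median was -0.62 (camera adjusted p = 2.0e-05; adjusted p = 0.853 with an estimated correlation). By edgeR, 0 of its genes were called over all genes and 1 higher and 4 lower adjusted over the list alone. Class II genes had a median of 0.69 over 9 tested members (camera adjusted p = 1.9e-04; adjusted p = 0.853 with an estimated correlation), 0 of them called by edgeR over all genes or over the list alone. Among them, H2-Aa had 0.81 (509 and 583 against 292 and 323 CPM) and the class II regulator Ciita 0.89. The class II rise was not particular to this class. List medians were 1.23 in mesothelial-, 0.69 in endocardial- and 0.37 in fibroblast-like nuclei. With fewer than 5 tested members they were 1.16 in endothelial-, 0.83 in T or NK- and -0.33 in B-like nuclei. Glucose metabolism genes had a median of 0.30 over 15, with 1.14 for the glycolytic gene Pgk1, and extracellular matrix genes -0.42 over 28, with -1.31 for the tenascin gene Tnxb. Their camera adjusted p was 0.0319 and 0.014, and adjusted p = 0.853 for both with an estimated correlation. The extracellular matrix median turned to 0.02 at a mitochondrial limit of 10%. The carry-over list of cardiomyocyte transcripts, which macrophages do not make, had a median of 0.63 (camera adjusted p = 0.0142; adjusted p = 0.853 with an estimated correlation). It was -1.13 without anti-Trem2-siSpp1 replicate 3, and Ryr2, for example, stood at 30.3 and 637 CPM in treated and 168 and 29.1 CPM in vehicle nuclei. The erythroid carry-over list had a median of 2.26 over 5 (camera adjusted p = 0.114), with 1 higher adjusted over the list alone, and -2.35 without anti-Trem2-siSpp1 replicate 1. If all cardiomyocyte transcripts in macrophage-like nuclei were free RNA, its share would be 19.6% and 30.02% in treated and 16.2% and 10.7% in vehicle libraries by the profile of barcodes with 10 to 100 UMIs, and 12.8%, 22.4%, 12.9% and 21.98% by that of 100 to 500. The recruited and osteopontin-associated macrophage list had a median of -0.37 over 17 (camera adjusted p = 0.178), with 1 higher and 1 lower adjusted over the list alone. Among higher genes the smallest p belonged to the antibody genes Jchain (5.71), Iglc2 (6.21) and Igkc (4.34). Most treated UMIs came from anti-Trem2-siSpp1 replicate 1, and the vehicle counts were low. Jchain had 81 and 1 UMIs in treated and 1 and 2 in vehicle libraries, and Iglc2 44 and 1 against 0 and 1. Among lower genes the smallest p belonged to the cilia gene Cfap299 (-3.90), the actin-severing protein gene Gsn (-1.55) and the RNA-binding protein gene Rbfox1 (-2.59). Of these, Gsn is also a marker of the fibroblast class and Rbfox1 a leading gene of the mesothelial-like clusters.

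None of 10728 genes passed edgeR's quasi-likelihood test in macrophage-like nuclei (smallest adjusted p = 0.074, for Jchain), 740 had an unadjusted p under 0.05, and DESeq2 called 3 higher and 0 lower. Without the filter on low counts edgeR called 54 higher and 39 lower. The 3 genes of DESeq2 were Jchain, Lars2 and Gm19951, of which Lars2 and Gm19951 were named after their values were seen. Jchain and Gm19951 are also leading genes of the set-aside cluster with haemoglobin, albumin and immunoglobulin genes, mostly from anti-Trem2-siSpp1 replicate 1. Treatment cannot be told apart from the difference in library quality for any of the 3. Of 200 genes changed in simulated counts for this comparison, the test recovered 90% at a log2 change of 2 but 10% at 1, 2% at -1 and 36% at -2. The simulation gave all genes the same dispersion and left out differences between libraries, so it can overstate recovery. In the real counts Jchain, at 5.71, did not pass edgeR's test. A smaller cluster led by Adgre4 and Fgr gave 69 of the 138 macrophage-like nuclei of anti-Trem2-siSpp1 replicate 1. It gave 100 of 435 and 130 of 1113 in vehicle replicates 4 and 7. This cluster raised 5 of the 14 macrophage markers, Mrc1 not among them, and was erythroid-like under the second naming version. With 4 nuclei from it and 16 from the larger cluster, anti-Trem2-siSpp1 replicate 3 entered with exactly 20 macrophage-like nuclei. Calls were 297 higher and 360 lower without it, 9 and 5 without anti-Trem2-siSpp1 replicate 1, 17 and 6 without vehicle replicate 4, and 0 and 0 without vehicle replicate 7. The resident list median was -0.23 without anti-Trem2-siSpp1 replicate 1 and -0.99 without replicate 3. Mrc1 is also among the markers that named the class.

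In fibroblast-like nuclei the treated libraries had higher values for cardiomyocyte genes and lower values for endothelial genes. The cardiomyocyte stress list had a median of 1.06 over 9 tested genes (camera adjusted p = 5.9e-08; adjusted p = 0.41 with an estimated correlation). It holds the natriuretic peptide gene Nppa, at 1.17 (3006 and 3201 CPM in treated, 1454 and 1301 CPM in vehicle). It also holds the natriuretic peptide gene Nppb, at 2.01 (20 and 3 UMIs against 25 and 13), and the muscle ankyrin repeat gene Ankrd1, at 1.90. The sarcomere list had 0.49 over 20, and gap junction and intercalated disc genes 0.24 over 14. Of the latter, the desmosomal cadherin Dsc2 was at 3.50, on 7 and 4 UMIs in treated and 6 and 1 in vehicle nuclei. Calcium handling genes had 0.23 over 17, and oxidative phosphorylation genes 0.14 over 23. In this order camera gave adjusted p = 2.5e-05, 0.0298, 0.0384 and 0.0092, and adjusted p = 0.536 for each with an estimated correlation. Beside these, the carry-over list of abundant cardiomyocyte transcripts, which shares Nppa, Ttn and Tnnt2 with the stress or sarcomere lists, had a median of 0.87 (camera adjusted p = 6.0e-10; adjusted p = 0.536 with an estimated correlation). Counted as free RNA in the same way, cardiomyocyte transcripts would put its share in fibroblast-like nuclei at 40.3% and 25.3% in treated and 16.7% and 11.1% in vehicle libraries by the 10 to 100 UMI profile, and 26.2%, 18.9%, 13.3% and 22.8% by that of 100 to 500. The endothelial activation list had a median of -0.62 over 12 (camera adjusted p = 1.6e-06; adjusted p = 0.41 with an estimated correlation), with -2.28 for the nitric oxide synthase gene Nos3, -1.49 for the flow-responsive factor Klf2 and -0.95 for the adhesion molecule Vcam1. Endothelial lipid uptake genes had -1.06 over 8, with -1.92 for Fabp5 and -1.06 for Fabp4, haemoglobin and other erythroid carry-over genes -1.16 over 5, and type I interferon genes -0.24 over 21. Class II genes had 0.37 over 7, with 1.41 for Cd74. For these lists camera gave adjusted p = 2.3e-04, 3.8e-06, 0.04 and 0.0068, and adjusted p = 0.536 for each with an estimated correlation. Fibroblast activation genes had a median of 0.26 over 23 (camera adjusted p = 0.189) and extracellular matrix genes 0.24 over 32 (0.0634).

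None of 11110 genes passed edgeR's test in fibroblast-like nuclei, 536 had an unadjusted p under 0.05, and DESeq2 called 5 higher and 0 lower. Without the filter on low counts edgeR called 107 higher and 87 lower. The 5 genes of DESeq2 were Igkc and Lars2, a mitochondrial leucyl-tRNA synthetase gene, with Gm19951, Cmss1 and Gm42418, named after their values were seen. Igkc, Gm19951 and Cmss1 are also leading genes of a cluster seen at the 10% mitochondrial limit. It held 1991 barcodes of anti-Trem2-siSpp1 replicate 1, with a median mitochondrial share of 7.29%. A difference in library quality thus cannot be told apart from treatment for these genes. The same holds for Lars2 and Gm42418, since the mitochondrial share differed between the groups. Lars2 was at 980 and 754 CPM in treated and 244 and 192 CPM in vehicle nuclei (log2 change 2.00, edgeR adjusted p = 0.406). Adjusted over the list alone, 3 cardiomyocyte stress, 2 class II and 1 gap junction gene were higher, and 3 endothelial activation, 3 erythroid and 2 lipid uptake genes were lower. Simulated changes, with the same limits, were recovered in 90% of genes at a log2 change of 2, 12% at 1, 14% at -1 and 42% at -2. Calls were 92 higher and 42 lower without anti-Trem2-siSpp1 replicate 3, 42 and 12 without vehicle replicate 4, 43 and 35 without vehicle replicate 7, and 0 and 0 without anti-Trem2-siSpp1 replicate 1. The calcium handling median turned to -0.07 and that of oxidative phosphorylation to -0.01 without anti-Trem2-siSpp1 replicate 3, and that of fibroblast activation to -0.80 without replicate 1. Oxidative phosphorylation also turned, to -0.64, with free RNA of barcodes with 100 to 500 UMIs subtracted, and endothelial lipid uptake to 0.43 with ComBat before clustering.

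In endothelial-like nuclei the 2 genes with the smallest p were Igkc, an antibody light chain gene, and Lars2. Igkc was at 329 and 60.4 CPM in treated and 11.7 and 9.98 CPM in vehicle libraries (log2 change 4.40, SE 0.575). Lars2 was at 939 and 921 against 255 and 258 CPM (1.86, SE 0.247). Each had an edgeR adjusted p of 0.0525. For neither gene can treatment be told apart from the difference in library quality between the groups. Endothelial lipid uptake genes had a median of 0.43 over 11 tested members (camera adjusted p = 0.0216; adjusted p = 0.945 with an estimated correlation). The lipase anchor gene Gpihbp1 had 0.91, the fatty acid translocase gene Cd36 0.69 and Fabp5 -0.93, and 0 members passed edgeR's test over all genes or over the list alone. The median turned to -0.35 under the second version of the naming rule. The cardiomyocyte carry-over list again had a positive median, 0.54, with 0.98 for Nppa (camera adjusted p = 0.0034; adjusted p = 0.945 with an estimated correlation). Read as free RNA, these transcripts would give it a share of 33.3% and 33.1% in treated and 22.1% and 12.5% in vehicle libraries by the 10 to 100 UMI profile, and 21.7%, 24.7%, 17.6% and 25.6% by that of 100 to 500. Among lower genes the smallest p belonged to the receptor gene Ror1 (-4.29), Cytl1 (-2.42), which is also a marker of the endocardial class, and Rybp (-2.38). The fold of Ror1 rests on 1 and 0 UMIs in the treated libraries, against 83 and 29 in vehicle. None of 6982 genes passed edgeR's test, 363 had an unadjusted p under 0.05, and DESeq2 called 5 higher and 0 lower: Igkc, Lars2, Igfbp3, Ighm and Gm42418, the last 3 named after their values were seen. With DESeq2's size factors in the edgeR fit Igkc and Lars2 passed, and without the filter on low counts edgeR called 13 higher and 5 lower. Simulated changes, with the same limits, were recovered in 92% of genes at a log2 change of 2, 16% at 1, 12% at -1 and 52% at -2. Calls were 31 higher and 33 lower without anti-Trem2-siSpp1 replicate 3, 23 and 6 without replicate 1, 7 and 1 without vehicle replicate 4, and 5 and 0 without vehicle replicate 7. The carry-over median was -0.68 without anti-Trem2-siSpp1 replicate 3.

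Cardiomyocyte-like nuclei, the class in which an effect on atrial rhythm genes would be looked for, were too few for the planned test, with 7 and 47 in the treated and 229 and 110 in the vehicle libraries. Their CPM of summed UMIs for Nppa were 6431 and 8834 in treated and 6432 and 6840 in vehicle libraries. In the same order, the cardiac myosin gene Myh6 stood at 6729 and 4742 against 8932 and 6378, and the connexin gene Gja5 at 0 and 33.2 against 52.95 and 69.99. Gja5 rests on 0 and 5 UMIs in treated and 38 and 15 in vehicle libraries. Its 0, from 7 nuclei with 43540 UMIs, does not show a lower level. Nppb stood at 689 and 206 against 194 and 308, and Ankrd1 at 1906 and 378 against 1646 and 784. No test was made on these values.

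The last comparison asks whether the genes that moved with siSpp1 in culture moved the same way in macrophage-like nuclei of the atrium. Of the 65 genes that rose in culture, 53 were tested in the nuclei, where their median log2 change was -0.09, with 23 above and 30 below 0 (edgeR camera across genes, p = 0.609; p = 0.593 with an estimated correlation). Of the 38 that fell, 30 were tested and had a median of 0.14, with 19 above and 11 below 0 (p = 0.3; p = 0.582 with an estimated correlation). Neither list passed the test, and none of the genes that fell by 2-fold or more on the tested scale in culture was abundant enough in these nuclei to be tested. The genes called in culture changed by a median of 0.19. For single genes this fit recovered 10% of simulated changes at 1 and 2% at -1. The comparison therefore cannot tell a small shared change from none.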

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

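The tests on chance, GC content, seed matches, RNA sensing and free RNA were chosen after the results they bear on had been seen, as were the second droplet profile and the counts of barcodes at the 10% mitochondrial limit, while those on plasma cells and on the mix of macrophage-like clusters were chosen before.

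The changes that siSpp1 brought in cultured macrophages were set against chance, a technical trend and responses to the siRNA itself. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes, the real one with 103, and the highest of the others gave 4. These counts argue against chance for the number of calls as a whole. They do not cover single calls, and they cannot tell siSpp1 from a difference in handling that follows the groups. The tables argue against a GC content trend as the whole cause, since 84.5% of the 103 genes stayed past the threshold with that trend removed from each library and 103 kept their sign. Silencing of other transcripts through seed matches stays open, because the siRNA's sequence is not given in the sources used here and the motifs with the lowest scores were rich in GC (80.9%, against 14% in the highest 100); 12 motifs of the Spp1 transcript lay in the lowest 1%, where 15.1 would by chance, and none in the lowest 10. Sensing of the transfected RNA could raise interferon genes and stays open as well, with a list median of 0.14 and 0 of 28 members past limma's test (camera adjusted p = 0.0568), and so does the loss of osteopontin, which a control without an siRNA cannot separate from either.

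Antibody genes were among the higher genes with the smallest p in treated nuclei of 3 classes that do not make antibodies: Igkc stood at 468 and 55.3 CPM of summed UMIs in treated and 8.76 and 20.8 in vehicle macrophage-like nuclei, 239 and 32.6 against 9.28 and 8.14 in fibroblast-like, and 305 and 56.5 against 10.9 and 9.16 in endothelial-like nuclei. Free RNA in the droplets may account for this, and the test did not settle it. Few treated barcodes had 10 to 100 UMIs, so that profile could test it only weakly there. Ranked by UMIs, anti-Trem2-siSpp1 replicate 1 fell from 195 at barcode 8608 to 11 at barcode 10357. Vehicle replicates 4 and 7 still held 115 and 60 at barcode 60000. In macrophage-like nuclei the log2 ratio of Igkc moved by 0.17, from 4.06 to 4.23, with the profile of barcodes with 10 to 100 UMIs subtracted. Its UMIs fell from 406 to 222 in anti-Trem2-siSpp1 replicate 1, and from 9 to 0 and 28 to 19 in vehicle replicates 4 and 7. The ratio moved by -1.16 with the profile of 100 to 500 UMIs. In fibroblast- and endothelial-like nuclei of anti-Trem2-siSpp1 replicate 1 both profiles removed every Igkc UMI (128 and 70). For plasma cells as the origin, 0 of the 4 genes Mzb1, Derl3, Tnfrsf17 and Txndc5 passed the floor in empty droplets of anti-Trem2-siSpp1 replicate 1; the bound set beforehand was wrong, as 33377 UMIs put that floor at 89.9 CPM, above the level of each gene in both vehicle libraries. The albumin gene Alb moved with them in anti-Trem2-siSpp1 replicate 1 alone (132, 43.6 and 55.3 CPM in fibroblast-, endothelial- and macrophage-like nuclei and 179.8 in its nearly empty barcodes, 0 in these classes of replicate 3), and RNA of other tissues and a change with treatment in antibody-making cells stay open, untested.

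Resident macrophage genes had a median log2 change of -0.62 in treated macrophage-like nuclei, a value that camera called with the preset correlation but not with an estimated one (adjusted p = 0.853). Without anti-Trem2-siSpp1 replicate 1 the median was -0.23, and without replicate 3 it was -0.99. The tables argue against a different mix of the 2 macrophage-like clusters as the whole cause, since the median was -0.52 in the larger cluster alone, where replicate 3 has 16 nuclei. Subtracting free RNA left it at -0.57 or -0.68, depending on the droplet profile, and a mitochondrial limit of 10% put it at -0.86. An effect of the treatment on resident macrophages and a difference in the quality of the nuclei between the groups cannot be separated with these 4 libraries and were not tested.

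Among the 97 genes of the bulk lists and names that were examined, 13 of 194 groups of 4 libraries held a value far from the other 3, where chance gives about 1 in 20 groups, or 9.7; they fall in 7 libraries. Tgfbi was at 178 CPM in siSpp1 replicate 2 (others 168 to 169), Cbx7 at 6.60 in vehicle replicate 3 (6.21 to 6.26), Cxcl10 at 2.01 in vehicle replicate 4 (0.631 to 0.848) and Itgb1 at 855 in vehicle replicate 3. Mcm5 was at 39.3 in siSpp1 replicate 1 (40.2 to 40.3), Hspa1b at 2.79 in siSpp1 replicate 3 (2.35 to 2.42), Gclm at 313 in vehicle replicate 1 (301 to 302) and S100a8 at 3.15 in siSpp1 replicate 3 (3.72 to 3.82). Chil3 was at 2313 in vehicle replicate 4 (2183 to 2191) and 2114 in siSpp1 replicate 1 (2191 to 2207), and Batf3 at 0.961 in siSpp1 replicate 4 (1.18 to 1.19). In siSpp1 replicate 4 the matrix genes Col1a1 (23.04, others 10.5 to 11.9) and Sparc (21.1, others 9.92 to 10.4) stood high together.

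Barcodes outside the comparisons formed clusters to which anti-Trem2-siSpp1 replicate 3 gave more barcodes than the other libraries. At a mitochondrial limit of 10%, a cluster with macrophage markers, led by Slpi, Cd5l, Timd4 and Prg4, held 647 barcodes of this library against 42 and 26 in the vehicle replicates 4 and 7 and 20 in anti-Trem2-siSpp1 replicate 1. A cluster with markers of developing T cells, Dntt, Satb1 and Themis, held 621, against 52, 68 and 4 in the same order. Its barcodes in replicate 3 held less of these markers per UMI. Dntt was at 79.1 CPM of summed UMIs there, against 314 and 161 in vehicle replicates 4 and 7. Satb1 was at 697 against 3465 and 2286. The barcode count alone therefore does not show more developing T cells. The cluster with cardiomyocyte markers set aside at the 5% limit held 2513 barcodes of replicate 3, against 407, 41 and 13.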

How the results depend on the processing

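Alternatives chosen after seeing the data are the removal of the GC trend, the 100 to 500 UMI droplet profile, the removal of high doublet scores, the naming and set-aside versions, the 10% mitochondrial limit, ComBat for tests of genes, the larger macrophage-like cluster alone and the shares without 1 library; the others were planned, and the cause of each change below was not tested unless it is stated.

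In the bulk data the direction of every named gene and list past the threshold held in every alternative run. Of 27 named genes called, 4 stayed past the threshold in all of them, and 381 of 486 comparisons were on the same side and 105 weaker; for the 5 lists called, 79 of 99 were the same, 20 weaker, and none was kept throughout. The nuclei are limited by 4 libraries and few nuclei: of 1441 comparisons of 77 lists, 1222 were the same, 76 weaker, 126 stronger and 17 reversed, and of 1246 for 69 named genes 1155 were the same, 90 stronger and 1 reversed. Depth limits Spp1 in macrophage-like nuclei, whose pooled log2 ratio ran from -2.14 (without vehicle replicate 4) to -0.61 (10% limit, no cluster set aside) where a ratio can be formed; without anti-Trem2-siSpp1 replicate 1 there are 0 treated UMIs and no ratio. Not run were the count test on recovered bulk reads, the macrophage- and endothelial-like tests at 1000 UMIs (19 nuclei in a library), the macrophage-like test under the second naming version (16), the list of genes changed by 2-fold or more in culture, which had 0 members tested in the nuclei, and the cardiomyocyte-like test in most settings. With clusters kept in the class of their markers that test gave 0 genes by edgeR (399 at an unadjusted p under 0.05), and at the 10% limit with no cluster set aside 0 (1820). In the latter setting, 1991 barcodes of anti-Trem2-siSpp1 replicate 1 in this class came from a cluster led by Alb, Jchain and Igkc.

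The bulk counts of 65 higher and 38 lower were 45 and 15 without the filter on low values, where more genes are tested, 37 and 18 in limma without the trend, and 2 and 5 with replicate number as a block, though the numbers do not pair the libraries (correlations of the same number between groups -0.03, -0.04, -0.09 and 0.04). Leaving out each library gave 21 (without siSpp1 replicate 3) to 52 higher (without siSpp1 replicate 4) and 10 (without siSpp1 replicate 3) to 43 lower (without vehicle replicate 1). Each of the other bulk alternatives gave counts within 1.5 times. Lists past the threshold numbered 5 with camera, 0 with an estimated correlation, 2 with fry (1 of them not among the 5), and 3 (without vehicle replicate 4) to 8 (without siSpp1 replicate 3).

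In nuclei edgeR called 0 genes in each class. DESeq2 called 5 higher in fibroblast-like, 5 in endothelial-like and 3 in macrophage-like nuclei, and the edgeR fit with DESeq2's size factors 2 and with ComBat 2 in endothelial-like nuclei. Without the filter on low counts there were 107 higher and 87 lower in fibroblast-like, 13 and 5 in endothelial-like, and 54 and 39 in macrophage-like nuclei. Leaving out 1 library gave 0 (without anti-Trem2-siSpp1 replicate 1) to 92 higher (without replicate 3) and 0 to 42 lower in fibroblast-like, 5 (without vehicle replicate 7) to 31 (without anti-Trem2-siSpp1 replicate 3) and 0 to 33 in endothelial-like, and 0 (without vehicle replicate 7) to 297 (without anti-Trem2-siSpp1 replicate 3) and 0 to 360 in macrophage-like nuclei.

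Lists past camera's threshold numbered 11, 2 and 5 in fibroblast-, endothelial- and macrophage-like nuclei. They were 0 in each with an estimated correlation, 7, 1 and 3 with the 100 to 500 UMI profile subtracted, 6 and 5 in the first 2 classes with the 10 to 100 UMI profile subtracted, and 4 and 5 after thinning. For endothelial- and macrophage-like nuclei they were 9 and 11 with ComBat, 10 and 9 at the 10% limit, and 10 and 11 with no cluster set aside as well, and 7 for endothelial-like nuclei under the second naming version. Leaving out 1 library gave 7 (without anti-Trem2-siSpp1 replicate 3) to 16 (without replicate 1), 1 (without vehicle replicate 7) to 11 (without anti-Trem2-siSpp1 replicate 1), and 3 (without vehicle replicate 7) to 15 (without anti-Trem2-siSpp1 replicate 1).

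Reversed medians in fibroblast-like nuclei were oxidative phosphorylation at -0.64 with the 100 to 500 UMI profile subtracted, and at -0.0147 without anti-Trem2-siSpp1 replicate 3 to 0.47 without replicate 1; endothelial lipid uptake at 0.43 with ComBat; calcium handling at -0.0724 without replicate 3 to 0.48 without replicate 1; and fibroblast activation at -0.80 without anti-Trem2-siSpp1 replicate 1 to 0.80 without vehicle replicate 7. In endothelial-like nuclei lipid uptake was at -0.35 under the second naming version, and without anti-Trem2-siSpp1 replicates 3 and 1 calcium handling ran from -0.48 to 0.60, sarcomere from -0.80 to 1.35 and cardiomyocyte carry-over from -0.68 to 1.496. In macrophage-like nuclei extracellular matrix was at 0.0201 at the 10% limit and 0.13 with no cluster set aside as well. Without anti-Trem2-siSpp1 replicates 3 and 1, gap junction genes there ran from -0.48 to 0.80, sarcomere from -0.98 to 1.43, atrial fibrillation loci from -0.56 to -0.15 (the direction camera gave turned), type I interferon from -0.69 to 0.36, cardiomyocyte carry-over from -1.13 to 1.45 and erythroid carry-over from 3.14 to -2.35. Ryr2 went from -1.67 without anti-Trem2-siSpp1 replicate 3 to 3.33 without vehicle replicate 4.

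Shares of nuclei, treated minus vehicle in percentage points, were 4.603 for cardiomyocyte-like, -5.65 for fibroblast-like, -0.300 for endothelial-like and 2.90 for macrophage-like. With clusters kept in the class of their markers they were 41.4, -10.3 and -2.62 in the first 3, and at the 10% limit with no cluster set aside 73.7, -15.0 and -5.01. In the last setting, 1991 barcodes of anti-Trem2-siSpp1 replicate 1 counted as cardiomyocyte-like came from a single cluster. That cluster had a median of 583 UMIs and was led by Alb, Jchain and Igkc, with no cardiomyocyte marker among its leading genes. ComBat gave -1.35 for cardiomyocyte-like, -1.27 for endothelial-like and 11.1 for macrophage-like, and resolution 0.5 gave -1.97 for fibroblast-like and 1.27 for endothelial-like. Endothelial-like nuclei were at 0.627 with 1000 UMIs, -2.82 with 300 UMIs and 200 genes, 9.78 at the 10% limit, -1.46 under the first and 10.6 under the second naming version. Without 1 library the differences ran from -0.868 (without anti-Trem2-siSpp1 replicate 3) to 10.1 (without replicate 1) for cardiomyocyte-like, -8.26 (without vehicle replicate 4) to -3.04 (without vehicle replicate 7) for fibroblast-like, -0.962 (without anti-Trem2-siSpp1 replicate 1) to 0.361 (without replicate 3) for endothelial-like, and -3.70 (without anti-Trem2-siSpp1 replicate 1) to 9.4996 (without replicate 3) for macrophage-like nuclei.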

Other observations

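The values in this part were chosen after they had been seen, except for the list tests, which were planned. In endocardial-like nuclei immediate early genes, transcription factors and others induced within minutes of a stimulus, had a median log2 change of -0.89 over 15 tested members (camera adjusted p = 8.2e-10; adjusted p = 0.768 with an estimated correlation), with Klf4 and Ier2 lower adjusted over the list alone. The class sits in different clusters per library: 208 of the 232 nuclei of anti-Trem2-siSpp1 replicate 1 came from 1 cluster, and a cluster led by the immediate early genes Fosb, Egr3, Egr1 and Fos held 123 nuclei of vehicle replicate 4 against 1, 0 and 6 in anti-Trem2-siSpp1 replicates 1 and 3 and vehicle replicate 7. The cardiomyocyte carry-over list had a median of 0.36 in this class (camera adjusted p = 0.0342; adjusted p = 0.839 with an estimated correlation). In mesothelial-like nuclei class II antigen presentation genes had a median of 1.23 over 6 (camera adjusted p = 0.0012; adjusted p = 0.852 with an estimated correlation), and H2-Ab1, H2-Aa, H2-Eb1 and Cd74 were higher adjusted over the list alone. In the same class endothelial activation genes had -0.52 over 11, and lists of other cell types also had negative medians, with -0.94 for endothelial lipid uptake, -0.52 for erythroid carry-over and -0.35 for resident macrophage genes. Camera gave these 4 lists adjusted p = 2.8e-06, 4.3e-04, 0.0129 and 0.0159, and adjusted p = 0.852 for each with an estimated correlation. The cardiomyocyte stress list had 0.34 (camera adjusted p = 0.0185; adjusted p = 0.852 with an estimated correlation). T or NK-like nuclei had medians of 0.69 over 20 oxidative phosphorylation genes and 0.81 over 8 glucose metabolism genes (camera adjusted p = 4.8e-04 and 3.0e-04; adjusted p = 0.742 for both with an estimated correlation). In the same nuclei the cardiomyocyte carry-over list stood at 1.70 (camera adjusted p = 2.5e-06; adjusted p = 0.742 with an estimated correlation). None of the genes in these 3 classes passed edgeR's test, with 590, 545 and 183 at an unadjusted p under 0.05.

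Spp1 UMIs were also counted in nuclei of other classes and in nearly empty barcodes. The latter stood at 9.33 and 17.95 CPM in vehicle replicates 4 and 7, so counts near these levels do not show which cells express it. The source of counts above these levels was not tested. Fibroblast-like nuclei of vehicle replicate 4 held 123 Spp1 UMIs (39.4 CPM of summed UMIs), against 9 in vehicle replicate 7 (5.24) and 0 in both treated libraries. T or NK-like nuclei of anti-Trem2-siSpp1 replicate 1 held 22 (91.0 CPM, 53 nuclei), and lymphatic endothelial-like nuclei of vehicle replicate 7 held 10 (64.6 CPM). Over all barcodes Spp1 was at 6.62 and 5.40 CPM in the treated and 8.81 and 11.8 CPM in the vehicle libraries, and Trem2 at 20.96 and 12.97 against 7.83 and 22.2. Dntt, a gene of developing lymphocytes, had 11 and 29 UMIs in T or NK-like nuclei of the treated (45.5 and 175 CPM) and 24 and 19 in those of the vehicle libraries (85.04 and 68.3 CPM). Nearly empty barcodes held 0 and 0 Dntt UMIs in the treated and 2.33 and 6.90 CPM in the vehicle libraries.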
